A study of Homo sapiens with 4 samples.

How the data were processed

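CLIP-seq libraries were made from formaldehyde-crosslinked HCT116 cells with DNase and MNase treatment and paired-end Illumina sequencing, per the labels' protocols. Samples were grouped by their titles into MTA1 (2 libraries) and Ctrl (2 libraries). Peak lists of 2 libraries, MTA1 replicate 1 and Ctrl replicate 2, were used, and the other 2 libraries were not analysed here. The deposited name of the list attached to Ctrl replicate 2 describes MTA1 peaks, which disagrees with the label, and the labels of that library and of MTA1 replicate 2 name no antibody. The deposited names number the lists as the second and the third MTA1 experiment, the third attached to MTA1 replicate 1, and how this relates to the replicate numbers is not given in the sources used here. The label was kept as the name of the library, and no comparison was read as MTA1 against IgG.

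Reads were aligned to GRCh38 with TopHat2, per the submitters' processing notes. The peak caller, its thresholds, any use of a control library, the removal of duplicates and the pooling of libraries are not given in the sources used here. The deposited lists give for each peak its position, strand, an identifier and a whole-number count of tags, which was not normalised. The list of Ctrl replicate 2 also gives, per the file headers, the largest height of each peak, a coverage signal with a median of 6 and a maximum of 386, its length, its summit and the authors' annotation of gene and region. Tag counts ranged from 3 to 890 in the MTA1 replicate 1 list, with a median of 9 (quartiles 6 and 15), and from 3 to 517 in the Ctrl replicate 2 list, with a median of 7 (5 and 11). The top 1% of peaks held 8.19% and 7.32% of the tags. The total number of reads per library is unknown, and the sum of tags within peaks depends on how many peaks were called. Peak starts were found to count from 0, since peak edges met annotated exon edges at start plus 1 and at the end, so 1 was added to each start and all positions are 1-based.

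Each peak was assigned by its midpoint to coding sequence, 5' UTR, 3' UTR, other exon, intron, antisense or intergenic, in that order of priority, and to 1 gene, with GENCODE 29 on GRCh38 (58780 genes). Where overlapping genes gave the same feature, protein-coding genes came first and then the lowest gene identifier. The authors' annotation gave the same gene identifier for 96.6% of 26420 peaks of the Ctrl replicate 2 list. Of the 1617 peaks it placed in introns, 72.9% were exonic in GENCODE 29. Overlap between lists required 1 nt on the same strand (bedtools 2.31.1) and was set beside 100 random placements of the peaks in the same gene. Edges and codons were set beside 20 placements in the exons of the same gene. Genes shared by the lists were set beside the number expected within 10 bins of gene length. The 22 gene lists, with 733 of 735 entries matched, were NuRD complex, mitotic spindle and chromosome segregation, DNA replication, DNA damage response, p53 target genes, Wnt signalling, SR proteins and hnRNPs, core spliceosome proteins, cytosolic ribosomal proteins, translation factors, glycolysis, chromatin modifiers, epithelial adhesion, mesenchymal genes, colorectal cancer driver genes, nuclear-retained lncRNAs, abundant small RNAs, mitochondrially encoded RNAs, replication-dependent histones, and markers of hepatocytes, of leukocytes and erythroid cells, and of neurons (long genes). Shares of genes with a peak were placed among 10000 random lists matched on gene length decile and gene type, which gave 44 percentiles that describe these lists and are not tests. Shares have exact (Clopper-Pearson) 95% binomial intervals for counting error only, since tags without molecular identifiers are not independent molecules. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

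The gene lists, the design, the rule for named genes and most alternatives were fixed before the data were examined. It took, for each list, the 10 genes with the most peaks, the 5 with the most peaks per kb among genes with at least 10 peaks and the genes of the 5 highest peaks. It also took the 5 genes with the largest difference in share of peaks in each direction, up to 4 members of each gene list with the most peaks, and MTA1. The third part was applied to tag counts, the only value per peak in both lists. HBE1 and HBG2 are named because their annotated spans overlap OR51B5. Genes named in the other observations outside this rule were chosen after their values were seen. Alternatives covered the minimum overlap, strand, peaks above the median tag count, equal numbers of peaks, touching peaks, the placement model, abundant RNA, the minimum of peaks per gene, gene sets, the source and weighting of annotation and the matching of random lists. Alternatives on the GENCODE basic set, on intron shares in genes with a peak in both lists and on k-mers of exonic peaks were added after the data were seen.

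The planned 5-mer composition of all peaks, with its alternatives, needed a genome sequence, which was not used here. A version for exonic peaks was made from transcript sequences after the data were seen. It used 92.4% of the exonic MTA1 replicate 1 peaks and 97.2% of the exonic Ctrl replicate 2 peaks, those that lay in 1 exon of a transcript, with random windows from the same UTR or coding region as background. That background replaced windows from anywhere in the transcript after a first result had been seen. The procedures were tested on simulated peaks. With no sharing, the overlap over chance was 0.992 where 1 was expected, for placement in exons or introns. Simulated peaks and chance used the same placement there, so this checked the code only and did not cover placement in the whole gene. A planted overlap of 19.92% was recovered as 19.86%. Of the midpoints, 99.4% of intronic and 100% of exonic ones were recovered, and 5.5% of random gene lists fell outside the central 95%.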

Results

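RNA associated with MTA1, a subunit of the NuRD nucleosome remodelling and deacetylase complex, was sampled by crosslinking, immunoprecipitation and sequencing (CLIP-seq) in HCT116, an epithelial cell line from a human colorectal carcinoma. Precipitation with IgG served as the control. The labels describe 4 libraries, 2 labelled MTA1 and 2 labelled Ctrl. Peak lists attached to MTA1 replicate 1 and to Ctrl replicate 2 were compared, and the other 2 libraries were not analysed here. A peak is a stretch of 1 strand of the genome covered by sequenced tags. The list of MTA1 replicate 1 held 55975 peaks with 736804 tags, and the list of the library labelled Ctrl replicate 2 held 27000 peaks with 264316 tags. The deposited name of the list attached to Ctrl replicate 2 describes MTA1 peaks, and the labels of that library name no antibody, so whether it is a control list was left open. The name of the list attached to MTA1 replicate 1 gives the third MTA1 experiment, which differs from its replicate number. Every direction given here therefore runs between the MTA1 replicate 1 list and the list attached to the library labelled Ctrl replicate 2, and not between MTA1 and IgG. With 1 list per label there was no replicate error and no test between conditions. Intervals are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only.

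The series title names primary RNAs, and the share of peaks in introns addressed that question. Introns held 12.3% of the MTA1 replicate 1 peaks (95% interval 12 to 12.6, 6894 peaks in 3803 genes) and 1.77% of the Ctrl replicate 2 peaks (1.62 to 1.93, 478 peaks in 358 genes), a 6.96-fold difference. Most peaks of both lists lay in annotated exons, 84.7% and 96.4%, which are part of unspliced RNA as well as of mature mRNA. Coding sequence held 57.5% of the MTA1 replicate 1 peaks and 61.1% of the Ctrl replicate 2 peaks, and 3' UTRs held 20.2% and 30.1%. The 5' UTRs held 2.49% and 2.88%, and exons outside coding transcripts held 4.46% and 2.26%. Peaks antisense to a gene made up 2.95% and 1.81%. Introns took 91.9% of the length of the genes with an MTA1 replicate 1 peak and 91.0% for Ctrl replicate 2, so introns were under-represented relative to length in both lists, with ratios of 0.134 and 0.0194. Protein-coding genes held 95.8% of the MTA1 replicate 1 peaks assigned to a gene, and long non-coding RNA genes held 3.20%, against 97.8% and 1.54% in the Ctrl replicate 2 list. Among peaks above the median tag count the intron shares were 6.10% and 1.08%. The submitters' own annotation of the Ctrl replicate 2 list placed 5.99% of its peaks in introns.

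**Figure D1:**
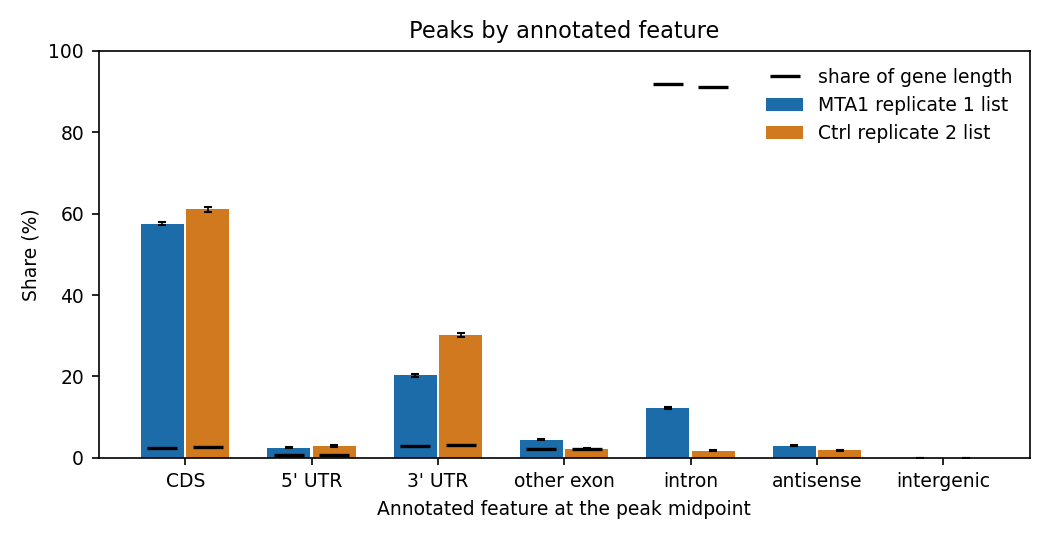
Share of peaks (%) by annotated feature at the peak midpoint in the MTA1 replicate 1 list (blue, 55975 peaks) and the list attached to the library labelled Ctrl replicate 2 (orange, 27000 peaks). Error bars are exact 95% binomial intervals and black dashes give the share of the length of genes with a peak that each feature takes; introns held 12.3% and 1.77% of the peaks.

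The intronic peaks of the MTA1 replicate 1 list were spread over many genes, with few in most of them. OR51B5 (ENSG00000167355.8, GRCh38 chromosome 11, 5303444 to 5505652, minus strand), an olfactory receptor gene whose annotated span overlaps 9 other same-strand genes, long annotated forms of HBE1 and HBG2 of the beta-globin cluster among them, had the most peaks, 59 with 57 in introns, against 16 and 13 in the Ctrl replicate 2 list. Intronic peaks within several overlapping protein-coding genes went to the lowest gene identifier, so some peaks counted for OR51B5 may lie equally in introns of those genes. HMGA2, which encodes an architectural chromatin protein, had 30 peaks with 28 in introns, against 10 and 5. TCF7L2, a transcription factor of the Wnt pathway, had 24 peaks, all intronic, against 18 peaks of which 1 was intronic. The long non-coding RNA genes PVT1 and FTX had 22 of 28 and 17 of 22 peaks in introns, and 0 of 5 and 1 of 1 in the Ctrl replicate 2 list. Above the median tag count, PVT1 had 10 and FTX 11 MTA1 replicate 1 peaks.

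The lists were also led by different genes. After OR51B5, the genes with the most MTA1 replicate 1 peaks were DDX60L with 43, NBEA with 40, the RAS regulator NF1 with 36, the DNA damage kinase ATM with 34, the myosin gene MYO9A with 33, WDFY3 with 32, and LYST and the adhesion receptor gene ADGRV1 with 31 each. The Ctrl replicate 2 list held 3 peaks in DDX60L, 0 in NBEA, 1 in NF1, 2 in ATM, 0 in MYO9A, 1 in WDFY3, and 0 in LYST and ADGRV1. The Ctrl replicate 2 list was led by the tight junction gene TJP1 with 53 peaks, PRKDC, the catalytic subunit of DNA-dependent protein kinase, with 52, the cadherin gene FAT1 with 42, DST with 41, the ubiquitin ligase gene HUWE1 with 38, the receptor kinase gene MET with 37, the dynein heavy chain gene DYNC1H1 with 32, and ITGA2, TRIO and NFAT5 with 31 each. These had 5, 1, 0, 11, 0, 1, 1, 0, 9 and 3 peaks in the MTA1 replicate 1 list, in the same order. Above the median tag count lay 27660 of the 55975 MTA1 replicate 1 peaks and 12514 of the 27000 Ctrl replicate 2 peaks. Among these, NBEA had 9 MTA1 replicate 1 peaks, ADGRV1 8 and LYST 10. These were smaller parts of their peaks than in the whole list, so their places depended on peaks of few tags. NF1 had 16 and MYO9A 17 such peaks, and ITGA2 had 18 Ctrl replicate 2 peaks, near or above the part for the whole list. A count of 0 listed peaks was not read as an absence of RNA, since the selection of the listed peaks is not given in the sources used here. By peaks per kb of gene, ABCF3 (1.5), KRI1 (0.849), KDM6B (0.806), ARFGAP2 (0.780) and INTS11 (0.763) led the MTA1 replicate 1 list. TRIB1 (1.24), NOLC1 (1.03), HYOU1 (0.999), SLC38A2 (0.954) and HNRNPUL2 (0.876) led the Ctrl replicate 2 list. MTA1 itself (ENSG00000182979.17, chromosome 14, 105419820 to 105470729, plus strand) had 4 MTA1 replicate 1 peaks and 13 Ctrl replicate 2 peaks, which says nothing about the precipitated protein.

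**Figure D2:**
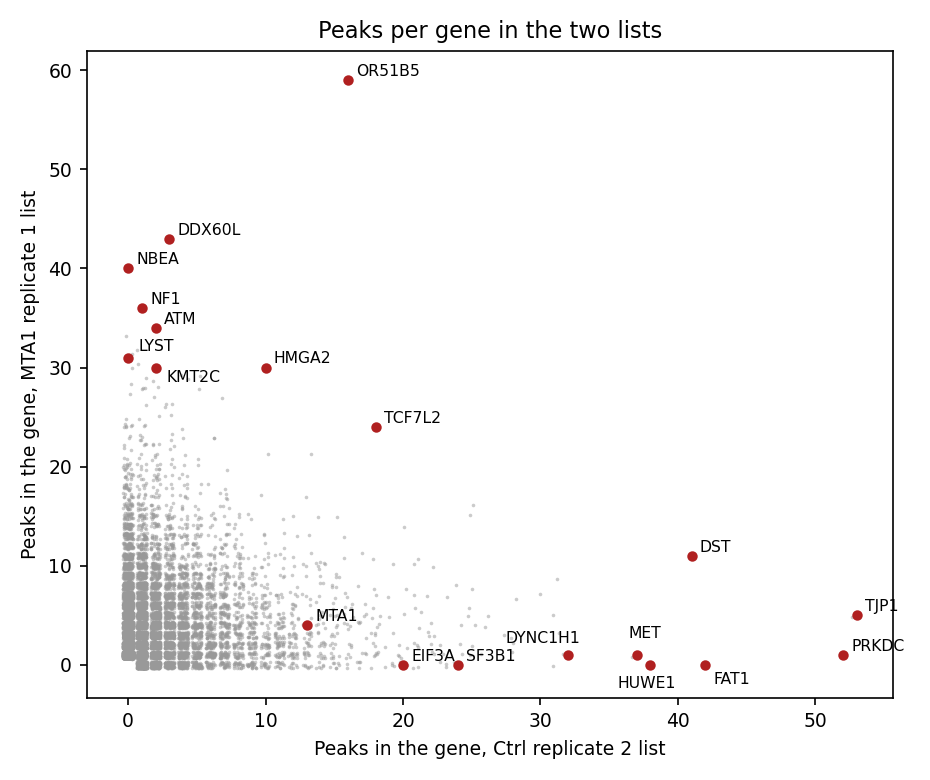
Number of peaks in each annotated gene in the Ctrl replicate 2 list (horizontal axis) and the MTA1 replicate 1 list (vertical axis), with grey points for 13316 genes, spread by a random shift of less than 1 peak for visibility, and red points for named genes. Genes with many peaks in 1 list lie along the axes, such as PRKDC with 52 Ctrl replicate 2 peaks and 1 MTA1 replicate 1 peak, and NBEA with 0 and 40.

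A peak was present in 12196 genes of the MTA1 replicate 1 list and in 7251 genes of the Ctrl replicate 2 list. Both lists held a peak in 6131 genes, 84.6% of the genes of the shorter list, against 3084 expected for independent draws within deciles of gene length, a ratio of 1.99. Among protein-coding genes alone the ratio was 1.46, with 5980 shared genes against 4085 expected. The number of peaks per gene was nearly unrelated over these 6131 genes, with a Spearman coefficient of 0.00913 across genes, which are not independent replicates. At the level of peaks, 4099 MTA1 replicate 1 peaks (7.32%, 95% interval 7.11 to 7.54) overlapped a Ctrl replicate 2 peak on the same strand, and 4320 Ctrl replicate 2 peaks (16%, 15.6 to 16.4) overlapped an MTA1 replicate 1 peak. For peaks within genes this was 8.02 and 7.90 times the share after random placement in the same gene. Placement within the exons or introns of the gene lowered the ratios to 1.97 and 1.90. That placement kept neither the position of peak edges on splice sites, described below, nor the preference for coding sequence. Both may account for some of the remaining excess, which was not tested. Requiring an overlap of 50% of both peaks left 3.22% and 6.68%.

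By the authors' tag counts, the highest MTA1 replicate 1 peaks lay in coding sequence of CCT7, a chaperonin subunit gene (chromosome 2, 73247762 to 73247926, 890 tags, and 73251226 to 73251432, 803 tags), in coding sequence of the chaperone gene HSPA8 (chromosome 11, 123058252 to 123058484, 639 tags), on the minus strand of the mitochondrial genome antisense to MT-ND1 (positions 3578 to 3986, 623 tags) and in coding sequence of the ATP synthase gene ATP5F1B (chromosome 12, 56639106 to 56639307, 606 tags). In the Ctrl replicate 2 list they lay in the mitochondrial tRNA gene MT-TP (15954 to 16023, 517 tags), in MT-CO3 (9706 to 9991, 496 tags), in MT-TI (4264 to 4399, 271 tags), in the vault RNA gene VTRNA1-2 (chromosome 5, 140718926 to 140719017, 226 tags) and in the 3' UTR of EIF4A2 (chromosome 3, 186789184 to 186789824, 217 tags). Of these, the CCT7 peak of 803 tags, the peak antisense to MT-ND1 and the ATP5F1B peak overlapped a peak of the Ctrl replicate 2 list, and none of the 5 Ctrl replicate 2 peaks overlapped a peak of the MTA1 replicate 1 list. Tag counts were used here to rank peaks within a list only.

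Gene groups encoding the RNA processing and translation machinery took a larger share of the peaks in the Ctrl replicate 2 list. The intervals treat peaks as independent draws, although several can lie in 1 gene, so they do not measure the spread between genes. SR proteins and hnRNPs, which bind pre-mRNA, held 0.189% of the MTA1 replicate 1 peaks (95% interval 0.155 to 0.229) and 0.837% of the Ctrl replicate 2 peaks (0.732 to 0.953). For core spliceosome proteins the shares were 0.238% (0.199 to 0.282) and 0.900% (0.791 to 1.02), with 0 and 24 peaks in SF3B1 and 16 and 7 in AQR. None of the 7 Ctrl replicate 2 peaks in AQR lay above the median tag count. Translation factors held 0.148% (0.118 to 0.184) and 0.852% (0.746 to 0.969), with 0 and 20 peaks in EIF3A, and 5 and 21 in EIF5B. Cytosolic ribosomal proteins held 0.172% (0.139 to 0.209) and 0.363% (0.295 to 0.442), in genes whose processed pseudogenes can share reads. Glycolysis genes held 0.0464% (0.0303 to 0.0681) and 0.285% (0.225 to 0.356), with 0 and 13 peaks in GPI. Epithelial adhesion genes held 0.157% (0.126 to 0.194) and 0.952% (0.839 to 1.07), with 1 and 26 peaks in the integrin gene ITGB4, and 1 and 20 in the desmosomal gene DSP. The NuRD complex held 0.116% (0.0896 to 0.148) and 0.322% (0.258 to 0.397), with 2 and 13 peaks in CHD4. DNA replication genes held 0.356% (0.308 to 0.408) and 0.852% (0.746 to 0.969), with 0 and 19 peaks in TOP1, although POLE and POLA1 each had 15 and 5, with 9 MTA1 replicate 1 peaks of POLA1 above the median tag count. Mitochondrially encoded RNAs held 1 and 8 peaks, with non-overlapping intervals of their shares.

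Chromatin modifiers went the other way by share of peaks, with 0.965% of the MTA1 replicate 1 peaks (0.885 to 1.05) and 0.767% of the Ctrl replicate 2 peaks (0.666 to 0.878). Among random lists drawn from genes with a peak in either list, their share of genes with a peak lay above the range for Ctrl replicate 2 (percentile 99.975). For MTA1 replicate 1 it lay within a range that reached 100% (percentile 78.11), so it could not lie above. KMT2C had 30 and 2 peaks and CHD7 27 and 2, while SMARCC1 had 1 and 25. Long neuronal genes, markers of a cell type other than the studied line, held 51 peaks (0.0911%, 0.0678 to 0.120) and 9 peaks (0.0333%, 0.0152 to 0.0633), 29 and 4 of them in LRP1B. Above the median tag count, the MTA1 replicate 1 peaks numbered 20 in KMT2C, 14 in CHD7 and 10 in LRP1B. For the other 11 lists the intervals of the shares overlapped. Mitotic spindle and chromosome segregation genes held 0.616% and 0.733% of the peaks, with 20 and 0 peaks in the kinesin gene CENPE, of which 9 MTA1 replicate 1 peaks lay above the median tag count. DNA damage response genes held 0.672% and 0.748%, with 26 and 3 peaks in ATR, against 1 and 52 in PRKDC. Colorectal cancer driver genes held 0.475% and 0.489% of the peaks, p53 target genes 0.170% and 0.137%, Wnt signalling genes 0.305% and 0.322%, and nuclear-retained lncRNAs 0.123% and 0.144%. Mesenchymal genes held 26 and 6 peaks (0.0464% and 0.0222%), replication-dependent histones 10 and 14 (0.0179% and 0.0519%), hepatocyte markers 22 and 3 (0.0393% and 0.0111%), and leukocyte and erythroid markers 3 and 1 (0.00536% and 0.00370%). None of the 23 genes of the list of spliceosomal snRNAs and other abundant small RNAs had a peak in either list.

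The share of a list's genes with at least 1 peak was set beside 10000 random lists matched on gene length and gene type. In the MTA1 replicate 1 list, 12 of the 22 gene lists lay above the central 95% of random lists and 3 below. For Ctrl replicate 2 the numbers were 15 and 3. The random lists were not matched on expression and could hold genes not expressed in these cells. A place above or below the range therefore does not show a preference in the precipitate. The lists below were, in both cases, the hepatocyte, leukocyte and erythroid, and long neuronal markers, with 20%, 4.00% and 23.3% of genes with an MTA1 replicate 1 peak. When only genes with at least 3 peaks counted, 9 lists lay above and 4 below for MTA1 replicate 1, and 12 and 4 for Ctrl replicate 2. The NuRD complex, core spliceosome proteins and cytosolic ribosomal proteins then lay within the range for MTA1 replicate 1. Ribosomal proteins, mitochondrially encoded RNAs and histones did so for Ctrl replicate 2. All 36 genes of SR proteins and hnRNPs and 14 of the 15 NuRD complex genes had a Ctrl replicate 2 peak, and 30 and 14 had an MTA1 replicate 1 peak. When random lists were drawn only from genes with a peak in either list, 5 gene lists lay below and 0 above for MTA1 replicate 1, and 12 above and 0 below for Ctrl replicate 2. For most lists the random range of MTA1 replicate 1 then reached 100%, so that they could not lie above it, and the absence of lists above it says little. Cytosolic ribosomal proteins then passed from above the range to below it in the MTA1 replicate 1 list.

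**Figure D3:**
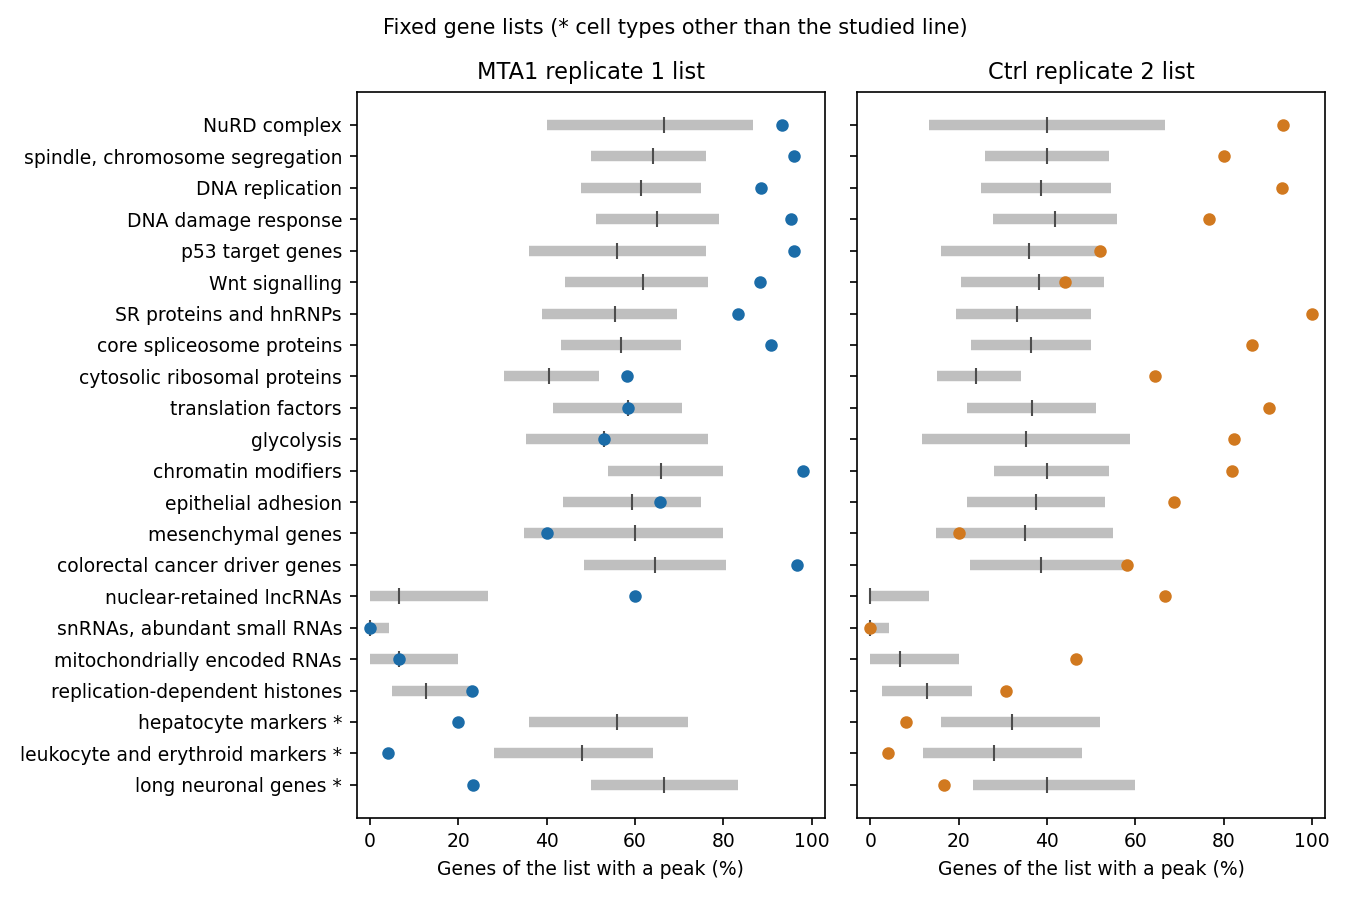
Share of the genes of each fixed gene list with at least 1 peak (%, points) in the MTA1 replicate 1 list (left) and the Ctrl replicate 2 list (right). Grey bars span the central 95% of 10000 random lists matched on gene length and gene type, and not on expression. Ticks mark their median and asterisks mark cell types other than the studied line. By percentile, 12 lists on the left and 15 on the right lie above the central 95%. Among the 15, colorectal cancer driver genes (percentile 98.0) lie on the end of their bar.

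Peaks in exons often began or ended exactly at a splice site. At least 1 edge lay on an annotated splice-site edge in 44.7% of the MTA1 replicate 1 peaks (95% interval 44.3 to 45.1) and 35.2% of the Ctrl replicate 2 peaks (34.6 to 35.7). Among exonic peaks the shares were 52.5% and 36.5%, against 0.516% and 0.530% after random placement in the exons of the same genes. A whole exon was covered edge to edge by 12% and 3.58% of the peaks. An exon edge was crossed, with at least 10 nt on both the exon and the intron side, by 3510 MTA1 replicate 1 peaks (6.27%, 6.07 to 6.47) and 508 Ctrl replicate 2 peaks (1.88%, 1.72 to 2.05). Stop codons were covered by 6.67% of the exonic MTA1 replicate 1 peaks and 5.49% of the exonic Ctrl replicate 2 peaks, against 3.88% and 2.79% after random placement. Start codons were covered by 3.95% and 3.62%, against 2.58% and 2.05%. Coding sequence held 22.7 and 22.4 times its share of gene length in peaks, and 3' UTRs 7.21 and 9.34 times. Random placement in exons did not keep this preference, which may account for some of the excess at codons and was not tested. The peaks differed in width, with medians of 93 nt (quartiles 64 and 130) and 57 nt (38 and 82), which affects how often a peak covers any given point.

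**Figure D4:**
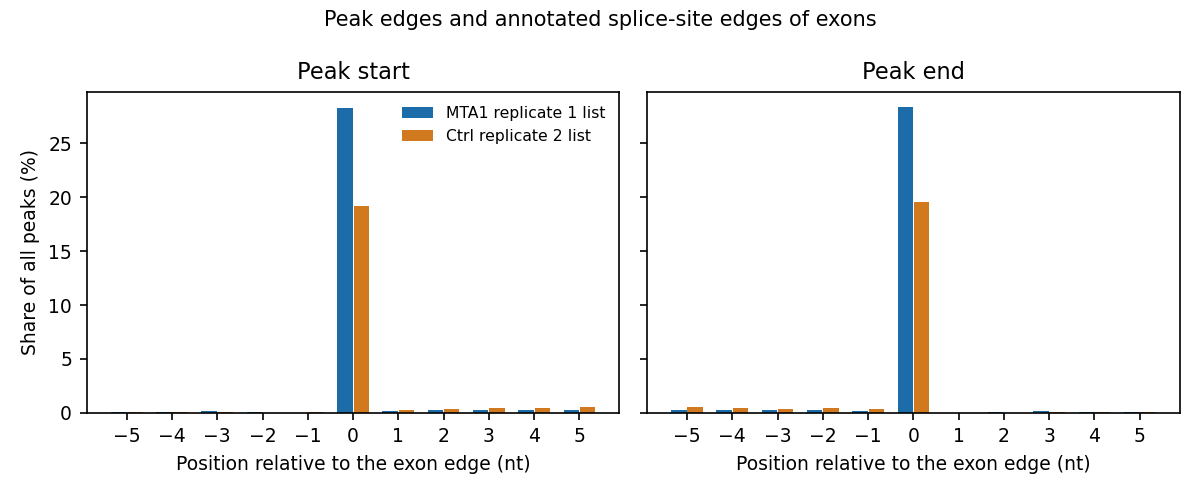
Share of all peaks (%) whose start (left) or end (right) lies at each position, in nt, relative to an annotated splice-site edge of an exon, for the MTA1 replicate 1 list (blue) and the Ctrl replicate 2 list (orange). At position 0 lie 28.3% and 19.2% of the peak starts and 28.3% and 19.6% of the peak ends.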

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

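Both tests of an explanation in this part were chosen after the result was seen. Peak identifiers of both lists end in a running number that rises with position along each strand of each chromosome, a value not used in the comparisons. It drew attention because the largest number was 966161 in the MTA1 replicate 1 list, above the 877265 of the list attached to the library labelled Ctrl replicate 2. The listed peaks were 5.79% and 3.08% of these numbers. If the numbers count regions found before a selection, which was inferred from their order and is not given in the sources used here, most regions were left out of both lists.

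With few reads in the MTA1 replicate 1 library of the 173 genes with at least 10 Ctrl replicate 2 peaks and at most 1 MTA1 replicate 1 peak, such as PRKDC, FAT1 and HUWE1, its identifiers would pass over no more numbers there than outside the genes. They passed over 1.81 times the number (bootstrap 95% interval 1.62 to 2.03 over 172 genes with a measurable window) predicted from the Ctrl replicate 2 numbers outside the genes, scaled by the totals, which argues against few reads as the whole cause. The same count was 0.756 times the expectation for the whole windows, so a smaller number of reads remains open, and the mirror set of 680 genes, with the lists exchanged, gave 1.39 (1.34 to 1.44) and 0.816, so the excess was not particular to these genes. A candidate explanation is that regions were left out with a higher bar in genes with many tags. The 90 MTA1 replicate 1 peaks left in these genes had a median of 24.5 tags. The median was 17 tags in the 358 other genes with at least 10 Ctrl replicate 2 peaks, weighted to the same Ctrl replicate 2 tags per gene. The ratio was 1.44 (bootstrap 95% interval 1.06 to 1.76). The 90 peaks came from genes chosen for having 1 peak, and were set against all 2014 peaks of genes with more than 1. The ratio can therefore exceed 1 without a higher bar and does not decide the explanation. Peaks left in the Ctrl replicate 2 list in the mirror set had a median of 4 tags, so passed-over numbers also occurred without such a bar and do not speak for it. A difference in precipitated RNA was not tested because there is 1 list per label.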

How the results depend on the processing

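The alternatives on the GENCODE basic set, on genes with a peak in both lists and on k-mers were chosen after seeing the data. No paired analysis was possible because the lists carry different replicate numbers and there is 1 list per label, and no replicate could be left out. The planned 5-mers of all peaks and their 3 alternatives (6-mers, flanking sequence, stricter peaks) were not run as designed. Merging touching peaks moved nothing because no peaks touch. Across the main results, 33 alternatives left the value within its interval or, for counts, within 1.5 times, and 34 moved it without a change of direction. Other values gave 519 and 152, with 1 reversed. Causes were not tested unless stated. The values below pair MTA1 replicate 1 and Ctrl replicate 2.

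With peaks above the median tag count, overlap was 4.88% and 11.3%, its ratio to chance 5.18 and 5.13, shared genes 2866 (fewer peaks enter), and intron shares 6.10% and 1.08%. Equal numbers of peaks gave 12% and 12.8%, and a ratio of 7.72 for MTA1 replicate 1. Placement in exons or introns gave ratios of 1.97 and 1.90, and overlap by 50% of both peaks 3.22% and 6.68%. Genes with at least 3 peaks in both lists numbered 2089. Intron shares weighted by bases were 14.2% and 2.26%, with the GENCODE basic set 14.9% and 2.43%, ignoring strand 13.6% for MTA1 replicate 1, in genes with a peak in both lists 12% for MTA1 replicate 1, and by the submitters' annotation 5.99% for Ctrl replicate 2. Drawn from genes with a peak in either list, 0 gene lists lay above the random range and 5 below for MTA1 replicate 1, and 0 below for Ctrl replicate 2, without the abundant small RNAs, which had no gene to draw. Its random range for MTA1 replicate 1 reached 100% for most lists, so the 0 above was largely fixed in advance. In that draw cytosolic ribosomal proteins fell to percentile 0 for MTA1 replicate 1. Matched on gene type only, 5 lists lay below for MTA1 replicate 1. The highest k-mer ratios of exonic peaks, 1.55 and 1.91, became 1.95 and 2.39 with 6-mers, 1.6 and 2.00 with windows from anywhere in the transcript, 1.67 and 2.12 with flanking windows, and 1.49 and 1.80 with peaks above the median tag count. GAACU led both lists except with 6-mers (UGUAGA and GACUGU) and flanking windows (GUAGA and UGUAG), where GAACU had 1.65 and 2.04. Depth limits peaks of few tags, since 3 was the lowest count listed.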

Other observations

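The genes named in this part outside the naming rule, the k-mer comparison, the 3 tests of the intron share and the tests of junction partners and of peak division were chosen after the patterns they address were seen. Intronic peaks were also frequent in MIR31HG, the host gene of a microRNA on chromosome 9 (21455642 to 21559669), with 15 MTA1 replicate 1 peaks and 25 in the list attached to the library labelled Ctrl replicate 2, all intronic. MIR100HG had 15 peaks in both lists, 11 and 5 of them intronic. SMYD3 and TRAPPC9 had 20 intronic peaks each in the MTA1 replicate 1 list, LINC00511 had 19, and CTBP2 and DOCK1 had 17 each, against 0, 0, 1, 0 and 0 in the Ctrl replicate 2 list. In that list ATXN3 had 7 peaks, all intronic, and the MTA1 replicate 1 list had 0 intronic peaks there.

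Small, structural and mitochondrial RNA genes taken as 1 class were more frequent in the Ctrl replicate 2 list. They held 0.332% of its genic peaks (95% interval 0.266 to 0.409) against 0.0755% (0.0542 to 0.102) in the MTA1 replicate 1 list. MicroRNA genes held 40 and 16 peaks and snoRNA genes 21 and 4, in this order, although the MTA1 replicate 1 list is the longer, while annotated snRNA genes and pseudogenes held 2 and 4, rRNA genes 4 and 5, and other small RNA genes, the vault RNAs VTRNA1-1 and VTRNA1-2 among them, 2 and 8. SNORD37 had the highest snoRNA peak of the MTA1 replicate 1 list with 122 tags. The vault RNA genes VTRNA1-1 and VTRNA2-1 had peaks of 115 and 197 tags in the Ctrl replicate 2 list. The median peak widths of 57 nt and 93 nt differ, and the lengths of the sequenced fragments were not analysed here.

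The higher intron share in the MTA1 replicate 1 list was weighed against 3 technical explanations. Weighting its peaks to the tag counts of the Ctrl replicate 2 list, as if tags of both lists meant the same depth, gave an intron share of 14.9% (bootstrap 95% interval 14.6 to 15.2). The upper bound for Ctrl replicate 2 was 1.93%. The share could hardly fall, since MTA1 replicate 1 intron peaks had a median of 6 tags, against 9 for that whole list and 7 for the Ctrl replicate 2 list. The weighting therefore shows only that the listed tag counts do not produce the difference, and a difference in depth stays open. Over the 6131 genes with a peak in both lists the mean within-gene share was 8.06 percentage points higher in MTA1 replicate 1 (bootstrap 95% interval 7.5 to 8.61), which argues against different genes. The GENCODE basic transcript set gave a ratio of 6.12 between the lists, which argues against the choice of GENCODE transcripts as the whole cause, although the submitters' annotation placed 5.99% of the Ctrl replicate 2 peaks in introns and exists for no MTA1 replicate 1 peak, so the size of the difference under that annotation is unknown. The antibody, the library preparation, the peak calling and the conflict between label and deposited name all stay open, since each label has 1 list.

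Peak edges on exon edges could come from reads spliced across junctions. By genome position, peaks ending on an exon edge had a peak starting on the edge joined to it across the intron in 38.0% of MTA1 replicate 1 cases (95% interval 37.3 to 38.8). For Ctrl replicate 2 the share was 37.9% (36.6 to 39.2). Peaks of the same genes ending short of the edge gave 16% and 15%, a difference that spliced reads predict. The peaks compared were matched on the set of genes only, and not on peaks or tags per gene. This may account for part of the difference, so it does not decide the explanation. Ends were taken by genome position on both strands, so donor and acceptor edges were not told apart. Division of peaks at annotated edges by the caller would leave few crossing peaks. An edge was crossed by at least 10 nt in 6.27% of MTA1 replicate 1 peaks and in only 1.88% of Ctrl replicate 2 peaks. In both lists no peak ending on an exon edge touched the next. No biological explanation was tested.

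The exonic peaks of both lists had similar 5-mer composition. GAACU had the highest ratio to random windows of the same transcript region in both, 1.55 (95% interval 1.52 to 1.59) for MTA1 replicate 1 and 1.91 (1.85 to 1.98) for Ctrl replicate 2. These intervals cover the counting error in the peaks only. They take the count in the random windows as exact and occurrences as independent, so they are too narrow for the ratio. For UGUAG the ratios were 1.5 and 1.87. CCCCC was lowest, at 0.607 and 0.421. Over 1022 5-mers the ratios of the lists had a Spearman coefficient of 0.907, across k-mers, which are not independent. The GC content of the peaks was 46.9% and 46.2%, against 47.9% and 46.9% in the random windows.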
